A study of Rattus norvegicus with 10 samples.

How the data were processed

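The series holds 10 one-colour Agilent gene expression arrays of rat submandibular gland, 5 from SHR and 5 from WKY, all from males aged 14 weeks per the labels. Per the labels' protocols, total RNA was extracted with Trizol, amplified and labelled with Cy3. The strain of each array came from the labels, which describe separate rats. A circular RNA profile of the same glands, which the series' design text mentions, was not analysed here.

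Per the file headers, the authors' scans were read with Agilent Feature Extraction, which subtracted the background and corrected trends across each array, and the processed signal is an intensity on a linear scale that was not normalised between arrays. The authors' deposited table holds log2 values of 30423 probes. All columns had the same median, 7.19, and the same 75th percentile, 8.79, as quantile normalisation between arrays gives. Its columns had a Pearson correlation across probes of at least 0.999 with the log2 processed signal of the same array, where probes are not independent replicates. How the authors made it is not given in the sources used here.

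Each array's log2 processed intensity was reduced by its 75th percentile over the non-control probes. Spots with an outlier mark from the scanner software were set to missing, which left 31 missing values among the kept probes, and spots of 1 probe were averaged (1390 probes were spotted 10 times). Probes well above background on at least 5 of the 10 arrays were kept, 29266 of 30367. Of all probes 18005 had 1 gene name, 0 had several and 12362 had none. Symbols came from RefSeq accessions in the gene table of assembly GRCr8, which matched 17935 of 19109 probes with an mRNA accession. Probes without a match had no gene name and were not tested as genes. For the 15168 named genes the brightest kept probe stood for the gene, and 14711 genes were tested. For a gene above background on 0 arrays of a strain, the fold is given as a lower limit: the bright strain's mean against the dim strain's mean of, per array, the higher of the probe's own value and the lowest signal among probes well above background. Where a gene was above background on only some arrays of a strain, their number is given.

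SHR was compared with WKY with limma (lmFit and eBayes, no covariates), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Tests were two-sided. For 33 gene lists, 725 members in all with 650 on the array, the median log2 difference was computed, and camera tested 32 lists with a preset correlation of 0.01. Camera with an estimated correlation, fry and an exact permutation test of each list's mean over the arrays were run beside it. The last of these was added after the data had been seen, and its smallest unadjusted p is 0.00794. It passed 7 lists, 2 of which camera also passed, and a single large change can move its score, which is a mean. The genes named are the 12 largest rises and the 12 largest falls among genes past the threshold whose strains do not overlap. They also include in each list up to 4 members with the largest changes past the threshold, or 2 members given as values where none passed. This gave 86 genes, 64 of them past the threshold; 4 of the 86 are counted but not reported here by name. The groups, the test, the lists, the naming rule and most alternatives were fixed before the data were examined.

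The alternatives were normexp background correction (offset 50) with quantile normalisation, quantile normalisation, scaling to the median, the authors' values, no filter or a filter on all arrays, outlier spots kept, the mean of all probes of a gene, every probe, a minimum of 1.5-fold, array weights, an intensity trend with robust variances, the slide as a block, the first title number as a random block and leaving out each array. The plan had assumed a mean signal column for normexp; the median signal was used. The slide as a random effect and a fit on slide 2 alone were chosen after seeing the data. Arrays scanned in 1 pass, by the scan time in the file headers, were taken as 1 slide, which gave 3 slides. No probe-level coordinates were used.

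The fit was tested on simulated data with the arrays' own spread over 14711 genes for the comparison of SHR minus WKY. Of 50 genes changed by each size, 42% were recovered at a log2 difference of 0.5, 88% at 1, 98% at 2 and 100% at 4, with 10 false calls among 174. A list moved by −0.5 was found at −0.40 and 0 other lists passed. Gene values in that simulation were independent, while on the arrays the estimated correlation was 0.20 within the interferon list and 0.53 within the macrophage list. The simulation therefore does not show how specific the list test is on these arrays. The versions were R 4.3.3, limma 3.58.1, the data.table package (1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.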

Results

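Messenger RNA was measured in the submandibular gland, a major salivary gland, of 10 male rats aged 14 weeks. The spontaneously hypertensive rat (SHR), an inbred strain that develops high blood pressure, was represented by 5 animals, and the Wistar-Kyoto rat (WKY), its normotensive control strain, by 5. Each rat had 1 one-colour Agilent array, named here by strain and the paired numbers of the sample title, such as SHR 3-3. On each array 42877 spots were read, of which 94.8% to 97.7% were well above background and 0 were saturated. The 75th percentile of the processed intensity lay between 333 and 648, and 14711 named genes were tested. The number of arrays limits the precision of every value. Slide 1 carried SHR 2-3, 3-1, 3-3 and 3-4, slide 2 carried SHR 2-1 with WKY 1-5, 4-1 and 4-2, and slide 3 carried WKY 1-2 and 1-3. Array SHR 3-3 stood apart from the other SHR arrays. In it 420 genes lay at least 2-fold below the mean of the other 4 SHR arrays, against 31 to 45 genes for each of those arrays, and 90 genes lay at least 2-fold above. SHR 3-3 also had the lowest 75th percentile (333), median signal (113) and share of spots well above background (94.8%) of the 10 arrays. Its mean correlation with its own strain, 0.975, was the lowest too. Whether array quality plays a part in its differences was not tested.

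The comparison asked which mRNAs differ in the gland between the hypertensive strain and its control. The largest rise in SHR was that of Cbr1, a carbonyl reductase, which was 71.6-fold higher (log2 difference 6.16 ± 0.16 SE, n = 5 per strain). Agtrap, whose product binds the type-1 angiotensin II receptor and promotes its internalisation, was 13.2-fold higher (3.72 ± 0.11). Smgc, which encodes submandibular gland protein C, was 17.1-fold lower (−4.10 ± 0.35) and Cyss, the salivary cystatin S, 16.7-fold lower (−4.06 ± 0.34). Genes induced by interferon and genes of the major histocompatibility complex (MHC) were lower as groups in camera with a preset correlation. Their adjusted p was 0.757 and 0.772 with an estimated correlation. In all, 222 genes were higher and 419 lower in SHR at a limma adjusted p below 0.05, 4.36% of those tested, and 2990 genes had an unadjusted p below 0.05. At least 2-fold changes numbered 28 upward and 96 downward. The groups did not overlap in 1066 of all 14711 genes tested, against the 0.794% of genes that chance gives. Of the 641 genes past the threshold, which were chosen by their difference, 566 did not overlap.

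The share of lower genes among the calls, 65.4%, was 55.9% with normexp background correction, 54.6% with quantile normalisation, 49.6% with scaling to the array median and 50.6% with the authors' values. With the slide as a block, 12 genes were higher and 32 lower, 35 of these 44 being among the 641. Without 1 array, the number of higher genes was 144 (SHR 3-4), 132 (WKY 1-2), 125 (WKY 1-3) and 144 (WKY 4-1), and the number of lower genes 239 (WKY 1-2), 218 (WKY 1-3) and 272 (WKY 4-1).

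After Cbr1, the largest rises besides Agtrap were those of Rhag, a membrane protein of the Rhesus family that transports ammonia, at 14.5-fold (log2 difference 3.86 ± 0.15 SE, n = 5 per strain), and Slc16a4, a member of the monocarboxylate transporter family, at 10.2-fold (3.36 ± 0.11). Tnnt2, the cardiac form of troponin T, was 8.63-fold higher (3.11 ± 0.34), with a log2 value of 3.65 ± 0.92 (SD) in SHR and 0.54 ± 0.15 in WKY. In SHR 3-3 it differed by −2.01 from the mean of the other 4 SHR arrays. Setd4, which lies next to Cbr1 in the genome and encodes a SET domain protein, rose 5.13-fold (adjusted p = 2.6e-08). Kcne2, a potassium channel subunit, rose 4.72-fold and Msln, the cell-surface glycoprotein mesothelin, 4.38-fold. Efnb2, the ligand ephrin B2, was 3.72-fold higher, from a WKY level well above background on 3 of 5 arrays. Rtel1, a DNA helicase that acts at telomeres, rose 2.98-fold, although another of its probes had a log2 difference of −0.54 (adjusted p = 0.0838). Ccn1, a matricellular protein, rose 2.76-fold, and Prnp, the prion protein, 2.74-fold. The call of Ccn1 (adjusted p = 0.0240) was lost without WKY 1-3, WKY 4-1 or WKY 4-2, with an adjusted p of up to 0.0609.

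Among genes above background on at least some arrays of both strains, the deepest falls were those of Cyp2j10, a cytochrome P450, at 38.6-fold (log2 difference −5.27 ± 0.26 SE, n = 5 per strain), and Pcyox1l, a prenylcysteine oxidase-like protein, at 27.0-fold (−4.76 ± 0.09). Cyp2j10 was well above background on 3 of 5 SHR arrays. Or4k44, an olfactory receptor gene, was above background on 0 of 5 SHR arrays and on all WKY arrays, and was at least 6.57-fold lower in SHR (adjusted p = 2.3e-09). Cyp11b3, a gene of the family of steroid hydroxylases, fell 20.1-fold. Cxcl13, the chemokine that attracts B cells, was 7.93-fold lower, Dmac2l 7.81-fold, Ms4a8 6.35-fold and Socs3, a feedback inhibitor of cytokine signalling, 5.93-fold. Of the MHC genes, RT1-T24-4 fell 6.72-fold and RT1-Db1 6.04-fold. A second probe of 3 of these genes showed a smaller log2 difference: −0.14 for Cyp11b3 (adjusted p = 0.631), −0.48 for Pcyox1l (0.0299) and −0.69 for RT1-Db1 (6.1e-04). With the slide as a block, 21 of the 24 genes with the largest changes passed; RT1-Db1 (adjusted p = 0.0737), Tnnt2 (0.0808) and Ccn1 did not.

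**Figure D1:**
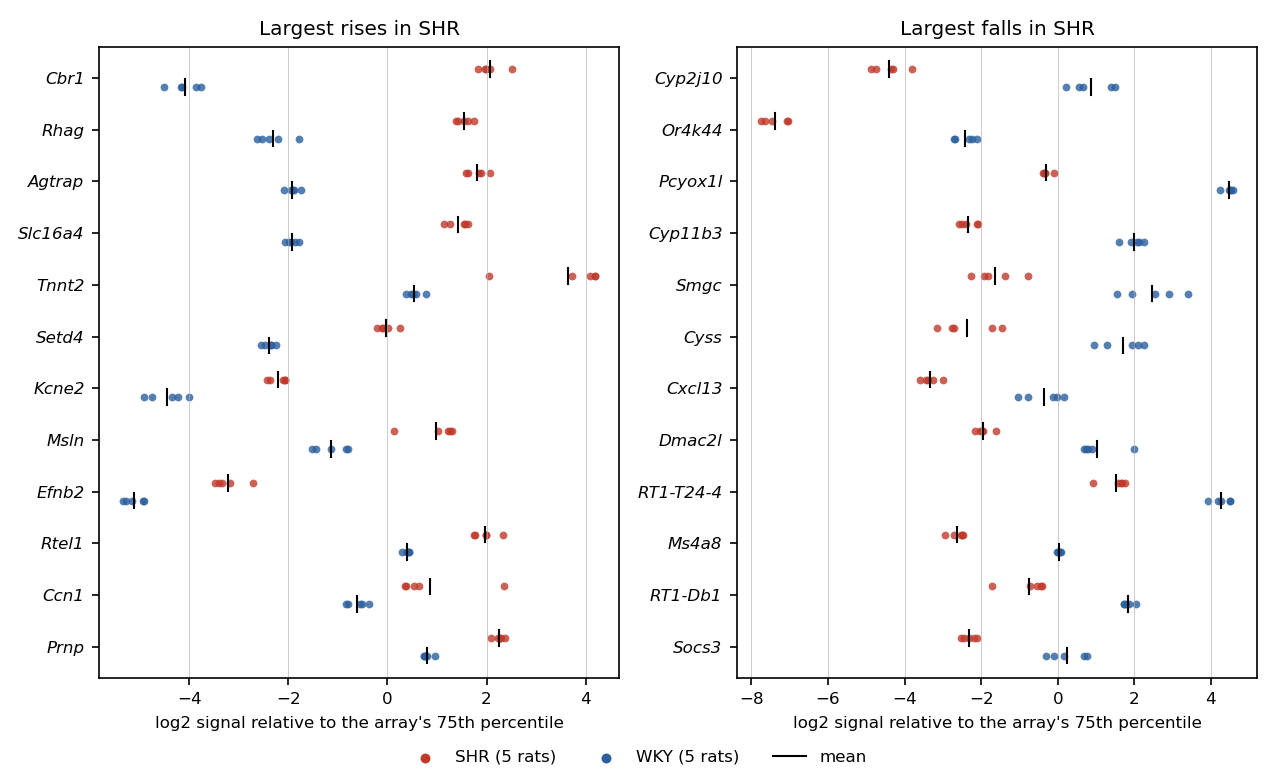
Log2 signal relative to the 75th percentile of each array (x axis) for the 12 genes with the largest rise and the 12 with the largest fall in SHR, 1 point per rat (5 SHR, red; 5 WKY, blue) and a black bar at each mean. No strain overlaps the other in any of these genes; Cbr1 lies at 2.07 in SHR against −4.09 in WKY on average, and Pcyox1l at −0.29 against 4.46.

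Genes of the interferon response were lower in SHR as a group, with a median log2 difference of −0.53 over 29 measured members (camera adjusted p = 9.3e-09; with an estimated correlation the adjusted p = 0.757). Of these, 12 fell, 0 rose and 17 did not pass, and adjusted over the list alone 19 fell. Irf7, the transcription factor that drives type I interferon production, fell by 1.53 ± 0.34 SE (n = 5 per strain), the antiviral protein gene Rsad2 by 1.29 ± 0.29, Ifi27 by 1.01 ± 0.20 and Isg15, a ubiquitin-like modifier, by 0.98 ± 0.20. In each of the 5 SHR arrays the list median lay below that of every WKY array, and the exact permutation test of the array scores gave an adjusted p of 0.0363. With the slide as a block, where the difference rests on SHR 2-1, the median was −0.50. Irf7 lost its call without WKY 1-3, WKY 4-1 or WKY 4-2 (adjusted p up to 0.0627), and Rsad2 without those or SHR 3-4 or WKY 1-2 (up to 0.0709).

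MHC and antigen processing genes had a median of −0.41 over 24 members (camera adjusted p = 1.8e-04; with an estimated correlation the adjusted p = 0.772), with 8 lower, 1 higher and 15 not past; adjusted over the list alone, 13 were lower and 2 higher. Besides RT1-T24-4 and RT1-Db1, RT1-CE16 fell by 1.55 ± 0.28 SE (n = 5 per strain) and the class II chain gene RT1-Da by 1.39 ± 0.33. The member that rose, named after its values were seen, was RT1-CE10 at 0.79 ± 0.12 (adjusted p = 0.00198). The exact permutation test gave an adjusted p of 0.0363. With the slide as a block, where the difference rests on SHR 2-1, the median was −0.29. The list value of SHR 3-3 differed by −0.62 from the mean of the other SHR arrays, and without it the median was −0.33 (adjusted p = 2.3e-04). RT1-Da lost its call without SHR 3-4 or any 1 of the 5 WKY arrays (adjusted p up to 0.0821).

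Markers of macrophages and dendritic cells were also lower, with a median of −0.44 over 16 members (camera adjusted p = 1.8e-04). With an estimated correlation the adjusted p = 0.772, with fry it was 0.107, and the exact permutation test gave 0.0635. Fcer1g, the common chain of activating Fc receptors, fell by 1.18 ± 0.21 SE (n = 5 per strain), the lysosomal glycoprotein Cd68 by 0.97 ± 0.17 and the actin-binding protein Aif1 by 0.81 ± 0.18, while 13 members did not pass; adjusted over the list alone, 5 fell. With the slide as a block, where the difference rests on SHR 2-1, the median was −0.49. Without SHR 3-3 the median was −0.27 (adjusted p = 0.00655). Aif1 lost its call without SHR 2-3, SHR 3-1, WKY 1-3, WKY 4-1 or WKY 4-2 (adjusted p up to 0.0851).

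Mast cell genes had a median of −0.27 over 10 members (camera adjusted p = 0.0184), although only Cpa3, the mast cell carboxypeptidase, fell by itself (−0.58 ± 0.13 SE, n = 5 per strain), also when adjusted over the list alone. With an estimated correlation the adjusted p = 0.772, with fry it was 0.0688, and the exact permutation test of the scores gave 0.0847. With the slide as a block, where the difference rests on SHR 2-1, the median was −0.25. The list missed the threshold without SHR 3-3 (median −0.25, adjusted p = 0.0528) or WKY 4-1 (−0.27, 0.0539), and with normexp its median was −0.04. Cpa3 was not past without SHR 2-3, WKY 1-2, WKY 1-3 or WKY 4-1 (adjusted p up to 0.0841), nor with normexp. Genes of T and NK cells had a median of −0.04 (camera adjusted p = 0.434), with 1 of 19 lower and 2 adjusted over the list alone. The one, the chemokine Ccl5, fell by 0.53 ± 0.13, a call lost without SHR 3-1, 3-3 or 3-4 or WKY 1-3, 1-5 or 4-1 (adjusted p up to 0.0995) and with normexp, median scaling or the authors' values. No B and plasma cell gene passed of 11, and 0 did adjusted over the list alone (median −0.07, camera adjusted p = 0.465); Tnfrsf17 had a log2 difference of −0.33 and Cd79b one of −0.25. Lymph node stroma and lymphoid chemokines had a median of −0.12 over 13 members (camera adjusted p = 0.0819). The exact permutation test of its scores gave an adjusted p of 0.0363. Cxcl13 was the 1 member that fell, also adjusted over the list alone, and in camera the list passed without WKY 1-3 (−0.20, 0.0314) or WKY 1-5 (−0.14, 0.0272).

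Among inflammatory cytokines and adhesion genes 3 of 26 fell, 6 adjusted over the list alone, and the list did not pass (median −0.07, camera adjusted p = 0.356). Il18 fell by 0.78 ± 0.13 SE (n = 5 per strain), the anti-inflammatory cytokine gene Il10 by 0.93 ± 0.20 and the chemokine Cxcl12 by 0.75 ± 0.16. Il10 differed by −0.16 and Cxcl12 by −0.22 with the slide as a block, where neither these nor Il18 passed. Il10 lost its call without SHR 2-3, 3-1 or 3-4 or WKY 1-2, 1-3 or 1-5 (adjusted p up to 0.0676), and Cxcl12 without SHR 2-3 or WKY 1-2, 1-3 or 1-5 (up to 0.0671). Without SHR 3-4 the list passed (median −0.15, adjusted p = 0.0189).

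**Figure D2:**
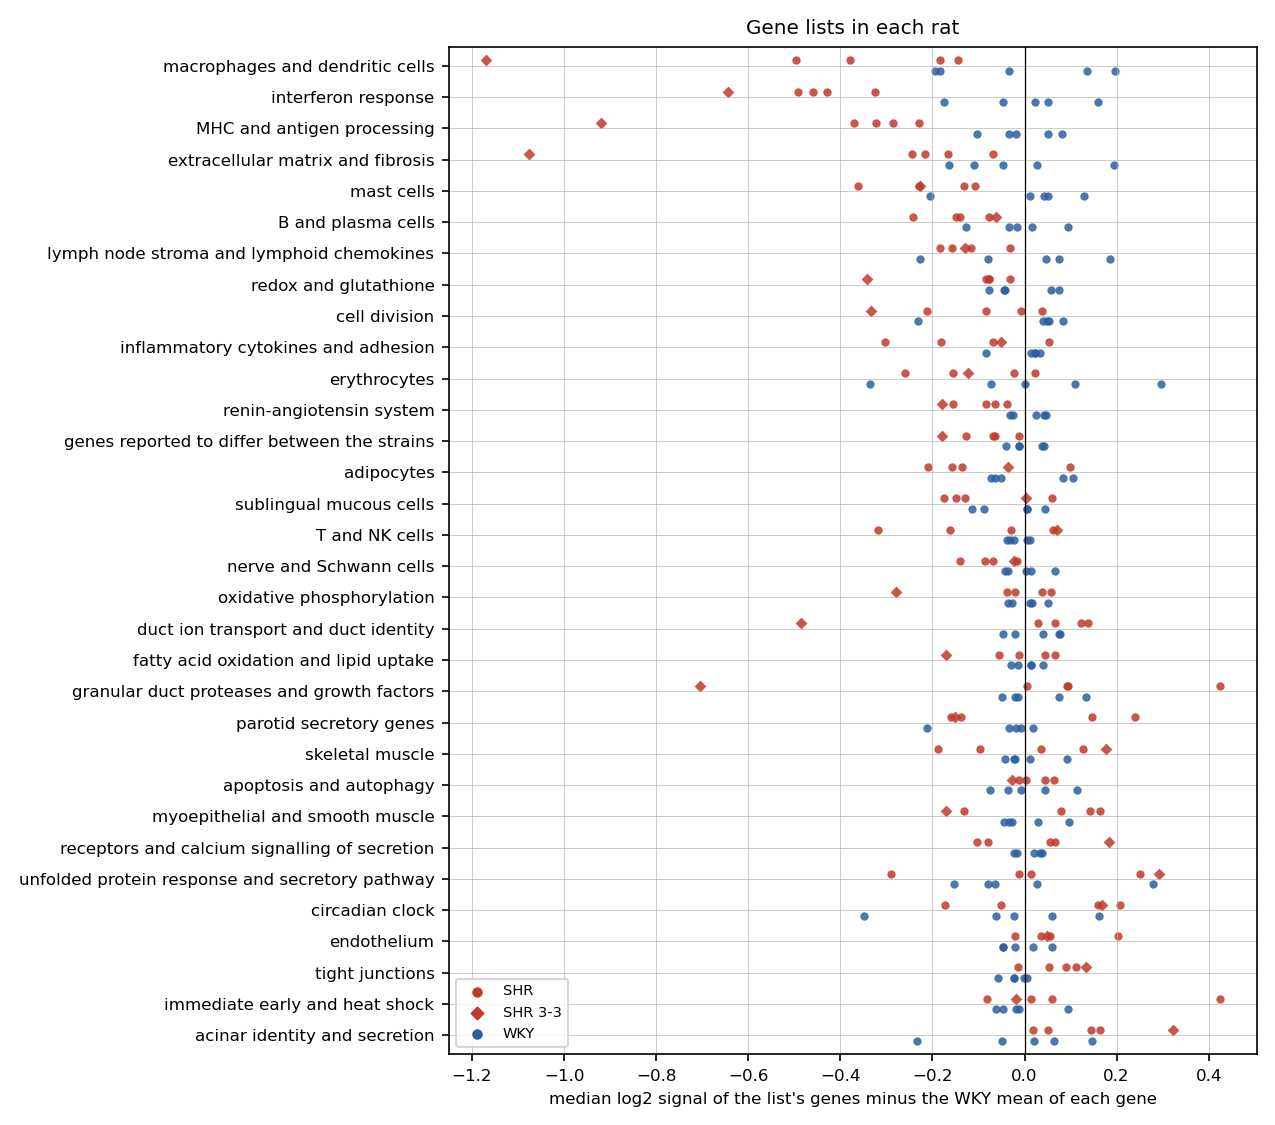
Median log2 signal of each gene list in each rat, after subtraction of the WKY mean of every gene (x axis), for 5 SHR (red, with SHR 3-3 as a diamond) and 5 WKY (blue); each point is 1 rat. The interferon list lies between −0.64 and −0.32 in the SHR arrays and between −0.18 and 0.16 in the WKY arrays, and SHR 3-3 reaches −1.17 for macrophages and dendritic cells.

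Acinar genes moved in both directions. Smgc and Cyss, with the proline-rich protein gene Prpmp5 (−1.73 ± 0.15 SE, n = 5 per strain), fell, whereas the opiorphin prepropeptide gene Oprpn rose by 0.61 ± 0.15; 16 of 20 members did not pass. Adjusted over the list alone, 4 rose and 5 fell. The list median was 0.19 and its mean −0.39, so that they differed in sign, and the camera test, directed upward, did not pass (adjusted p above 0.98). The exact permutation test of the list scores, which follow the mean and so the large falls, gave an adjusted p of 0.0363. Oprpn was not past without SHR 2-1, 2-3 or 3-4 or any 1 of the 5 WKY arrays (adjusted p up to 0.106), nor with normexp, quantile normalisation or the authors' values. None of the 14 granular duct proteases and growth factors passed, also adjusted over the list alone (median −0.11, mean −0.22, camera upward at an adjusted p of 0.943). The kallikrein gene Klk1c12 had a log2 difference of −1.86 and Egf, epidermal growth factor, one of −0.96. In SHR 3-3 they differed by −5.09 and −4.31 from the mean of the other SHR arrays. Without that array the list median was 0.14 (camera adjusted p = 0.174), and 1 member was lower and 1 higher past the threshold. Genes of duct ion transport and duct identity had a median of 0.03 and a mean of −0.04 (camera upward, adjusted p = 0.862). Of 23 members only the bicarbonate cotransporter Slc4a4 fell (−0.47 ± 0.10), also adjusted over the list alone, a call lost without WKY 1-2 (adjusted p = 0.0555). SHR 3-3 differed by −0.57 from the other SHR arrays in this list. Without SHR 3-3 the median was 0.05 (camera adjusted p = 0.0528), and 1 member was lower and 2 were higher past the threshold.

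Parotid secretory genes, 11 in all, had a median of −0.15 and a mean of −0.04 (camera upward, adjusted p above 0.98). Oprpn, shared with the acinar list, rose, a call that depended on the same arrays (0.61 ± 0.15 SE, n = 5 per strain), and the proline-rich protein gene Prb3 fell by 0.64 ± 0.12, a call lost with normexp; adjusted over the list alone, 2 rose and 1 fell. No member passed in the lists of sublingual mucous cells (7 members, median −0.09, camera adjusted p = 0.465; Cst5 −0.38, Tff2 −0.15) or of myoepithelial and smooth muscle cells (16 members, 0.01, 0.465; Myh11 0.33, Tp63 0.28). Adjusted over the list alone, 0 passed in both. Plvap, a component of endothelial fenestrae, was the 1 of 15 endothelial genes that rose (0.60 ± 0.15), also adjusted over the list alone. The endothelial list had a median of 0.05 (camera adjusted p = 0.356), which became 0.17 with the slide as a block, where the difference rests on SHR 2-1. Plvap lost its call without SHR 2-1, 2-3, 3-3 or 3-4 or WKY 1-2, 1-3, 4-1 or 4-2 (adjusted p up to 0.109).

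Extracellular matrix and fibrosis genes were lower as a group, with a median of −0.37 over 25 members (camera adjusted p = 0.0160). With an estimated correlation the adjusted p = 0.772, with fry it was 0.274, with array weights 0.0941 and in the exact permutation test of the scores 0.162. Col1a1, a chain of type I collagen, fell by 0.79 ± 0.20 SE (n = 5 per strain), the only member to pass, also adjusted over the list alone. The median was −0.29 with the slide as a block, where the difference rests on SHR 2-1. Array SHR 3-3 differed by −0.90 from the other SHR arrays; without it the median was −0.17 (adjusted p = 0.174), and without WKY 4-1 it was −0.31 (0.0835). Col1a1 lost its call without SHR 3-1, 3-3 or 3-4 or WKY 1-2, 1-3, 1-5 or 4-1 (adjusted p up to 0.103), and with normexp or scaling to the median. Another of its probes had a log2 difference of −0.19 (adjusted p = 0.360).

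Nerve and Schwann cell genes had a median of −0.03 over 19 members (camera adjusted p = 0.434), and the neural cell adhesion molecule Ncam1 was the 1 that fell (−1.46 ± 0.15 SE, n = 5 per strain), also adjusted over the list alone. The exact permutation test of the list scores gave an adjusted p of 0.0363. No member passed, over all genes or adjusted over the list alone, among skeletal muscle genes (15 members, median −0.03, mean −0.02, camera upward at an adjusted p of 0.943; Tnnt1 −0.65, Ckm 0.49), adipocyte genes (15, −0.07, 0.489; Lpl −0.63, Cidea −0.44) or erythrocyte genes (9, −0.12, 0.465; Ahsp −0.36).

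The renin-angiotensin system list held rises and falls of single members. Besides Agtrap, Enpep, the aminopeptidase that degrades angiotensin II, rose by 0.79 ± 0.10 SE (n = 5 per strain) and Ace, the angiotensin-converting enzyme, by 0.52 ± 0.10. The receptor gene Agtr1b fell by 0.71 ± 0.15, and so did the peptidase gene Nln, named after its values were seen, by 0.52 ± 0.08, while 13 of 18 members did not pass; 3 rose and 3 fell adjusted over the list alone. The list median was −0.18 and the mean 0.08, which differ in sign, and camera, directed downward, gave an adjusted p of 0.889. Of the receptors and calcium signalling genes of secretion, the VIP receptor Vipr1 (−0.58 ± 0.08) and the alpha-2A adrenoceptor Adra2a (−0.76 ± 0.18) fell, with 28 of 31 not past; adjusted over the list alone, 3 rose and 4 fell. The list had a median of 0.02 and a mean of −0.03 (camera upward, adjusted p = 0.735). Adra2a lost its call without SHR 2-3 or any 1 of the 5 WKY arrays (adjusted p up to 0.0875), and under each of the 4 other scalings.

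Of 22 tight junction genes, Ocln, occludin, rose by 0.47 ± 0.09 SE (n = 5 per strain), and 20 did not pass (median 0.08, camera adjusted p = 0.331). Adjusted over the list alone, 3 rose and 1 fell. Among 34 redox and glutathione genes, the sulfiredoxin gene Srxn1 rose by 1.04 ± 0.15, and the glutathione transferase Gstm1 (−2.01 ± 0.21) and the NADPH oxidase subunits Ncf1 (−0.45 ± 0.10) and Cyba (−0.43 ± 0.11) fell, with 1 rising and 4 falling adjusted over the list alone (median −0.10, camera adjusted p = 0.239). SHR 3-3 differed by −0.27 from the other SHR arrays in this list, and the exact permutation test of the list scores gave an adjusted p of 0.0363. Ncf1 was not past without WKY 1-2 or 4-1 (adjusted p up to 0.0583) and Cyba without any 1 array but SHR 3-4 (0.106), nor with normexp or median scaling.

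Oxidative phosphorylation genes had a median of −0.03 over 45 members (camera adjusted p = 0.656). The complex I subunits Ndufa10 (−0.73 ± 0.09 SE, n = 5 per strain) and Ndufb8 (−0.60 ± 0.08) fell, and 43 did not pass; adjusted over the list alone the counts were the same. With the slide as a block, where the difference rests on SHR 2-1, the median was −0.07. SHR 3-3 differed by −0.29 from the other SHR arrays. Of 26 fatty acid oxidation and lipid uptake genes, Cd36, the fatty acid translocase, fell by 1.02 ± 0.09 and 25 did not pass (median 0.00, mean −0.05, camera upward at an adjusted p of 0.943); 1 rose and 1 fell adjusted over the list alone. Among 13 genes reported to differ between these strains in other tissues, 2 rose and 3 fell, also adjusted over the list alone. Those named were Gstm1, Cd36, the secretory granule protein gene Chga (−0.84 ± 0.12) and the renal dipeptidase gene Dpep1 (0.71 ± 0.09), and the list did not pass in camera (median −0.03, adjusted p = 0.465), while the exact permutation test of its scores gave an adjusted p of 0.0363.

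In the apoptosis and autophagy list the autophagosome protein gene Map1lc3b rose by 0.79 ± 0.10 SE (n = 5 per strain), with 25 of 27 not past (median 0.01, camera adjusted p = 0.465) and the same counts adjusted over the list alone. No member passed, over all genes or adjusted over the list alone, in 4 lists. These were cell division (24 members, median −0.16, camera adjusted p = 0.0819; Ccne1 −0.50, Tyms −0.34), immediate early and heat shock genes (24, 0.14, 0.356; Egr2 0.49, Klf4 0.46), the unfolded protein response and secretory pathway (23, −0.01, 0.877; Trib3 −0.50, Dnajb9 −0.42), whose camera test was directed upward, and the circadian clock (15, 0.02, 0.943; Ciart −0.76, Npas2 0.49), whose mean was −0.03. Ciart and Npas2 varied widely within each strain, with SDs of 2.14 and 1.88 in SHR and of 2.25 and 1.67 in WKY. Cell division passed without SHR 2-1 (−0.23, adjusted p = 0.0498), SHR 2-3 (−0.19, 0.0267), SHR 3-1 (−0.18, 0.0335) or WKY 1-5 (−0.21, 0.0151). Of the sex-linked genes listed, 0 were measured.

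Strain and slide overlapped in this series. Slide 2 was the only one with both strains, so the blocked difference of a gene rests on SHR 2-1 against WKY 1-5, 4-1 and 4-2. Cbr1 had a blocked difference of 6.25 ± 0.30 SE, Agtrap 3.48 ± 0.19, Pcyox1l −4.87 ± 0.18 and Smgc −4.38 ± 0.55. Of the 64 genes named by rule that passed the threshold, 21 also passed with the block, all of them among the 24 largest changes, and no other list member did. The blocked difference was −0.23 for Agtr1b and −0.36 for Col1a1. Of the genes called from slides 1 and 3 alone, all 35 higher ones and 63.9% of the 241 lower ones had the same sign on slide 2. Within slide 2 the mean log2 difference was −0.47 for the interferon list, −0.46 for the MHC list, −0.41 for macrophages and dendritic cells, −0.29 for the extracellular matrix and −0.26 for mast cells, each resting on 1 SHR array. Slides 1 and 3 held 1 strain each and give no difference between strains. Within WKY, slide 3 minus slide 2 was −0.06 for the interferon list, 0.00 for MHC and −0.17 for macrophages and dendritic cells, and within SHR, slide 1 minus slide 2 was −0.10, −0.18 and −0.16, the latter resting on SHR 2-1.

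**Figure D3:**
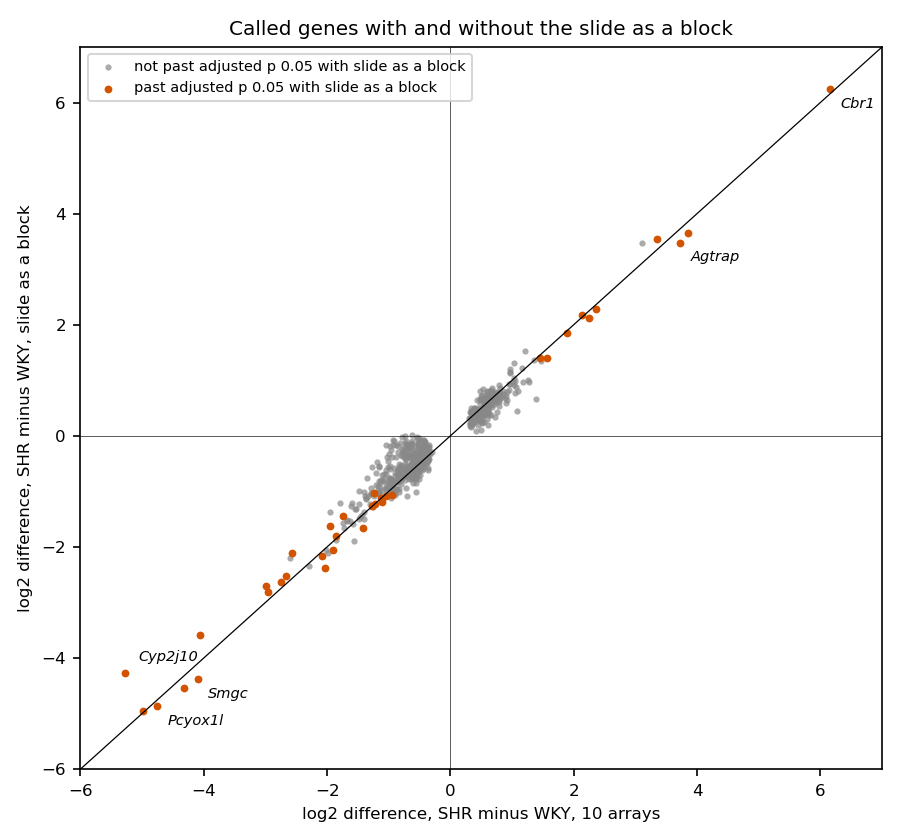
Log2 difference between SHR and WKY over all 10 arrays (x axis) against the difference with the slide as a block (y axis), 1 point for each of the 641 genes past adjusted p 0.05, with the line of equality; the 35 orange genes also passed with the block and the grey ones did not. Cbr1 lies at 6.16 and 6.25, and Cyp2j10 at −5.27 and −4.28.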

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

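The tests of the slide, of 1 SHR array and of leukocyte numbers in this part were chosen after the results had been seen, and the counts of other splits of the arrays before.

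Within each strain, 244 groups of 5 values (named genes, gene lists and array measures) were searched for 1 array far from the other 4. The search found 26, where chance alone gives about 12.2, and 17 of them were SHR 3-3; 25 of the 26 are given here. Values are log2 differences from the mean of the other 4 arrays of the strain. In SHR 3-3 they were −5.09 for Klk1c12, −4.31 for Egf, −2.01 for Tnnt2, −1.93 for RT1-Da, −1.90 for Irf7, −1.20 for RT1-Db1, −1.11 for Fcer1g, −1.06 for Msln, −0.98 for Adra2a, −0.96 for Isg15 and −0.74 for RT1-T24-4. For gene lists in SHR 3-3 they were −0.90 for extracellular matrix and fibrosis, −0.62 for MHC and antigen processing, −0.57 for duct ion transport and duct identity, −0.29 for oxidative phosphorylation and −0.27 for redox and glutathione. On the first principal component, which held 37.6% of the variance, SHR 3-3 had a score of −46.5.

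Other arrays stood apart in single measures. WKY 4-1 differed by 0.27 for Cyba, WKY 1-2 by 1.23 for Dmac2l, SHR 2-3 by 0.25 for Pcyox1l and SHR 3-4 by 1.87 for Ccn1. Among gene lists, SHR 3-4 differed by 0.43 for immediate early and heat shock genes, WKY 1-5 by −0.29 for cell division and −0.11 for inflammatory cytokines and adhesion, and WKY 1-3 by −0.20 for parotid secretory genes.

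The interferon, MHC and macrophage lists, which share 0 members with each other, were lower in SHR in camera with a preset correlation, though not with an estimated correlation (adjusted p = 0.757, 0.772 and 0.772), and macrophages missed the threshold in fry (0.107). Without SHR 3-3 all 3 lists still passed at the preset correlation, with medians of −0.46, −0.33 and −0.27. That test decides little, since it passed 5 or more lists in 74 of 100 splits of the arrays, the real one included. For interferon and MHC, the list median of every other SHR array also lay below that of every WKY array, so SHR 3-3 alone does not account for these shifts. For macrophages the other SHR arrays overlapped with WKY, and the part of SHR 3-3 stays open. Against the slide speak the differences within slide 2 (−0.47, −0.46 and −0.41) and those between slides 3 and 2 within WKY (−0.06, 0.00 and −0.17, against −0.52, −0.60 and −0.47 between the strains), but the former rest on SHR 2-1 alone and the latter leave out slide 1, so slide and strain cannot be told apart for these lists. Fewer leukocytes of all kinds also remains open, as the macrophage score was −0.49 over 15 members and the T and NK cell score −0.11 over 19, a difference with an exact permutation p of 0.0714. A strain difference in these genes, or in the cells that carry them, is an explanation the design offers, and it was not tested further. For the MHC list a strain variant under the probes, raised below for single genes, stays open too. The first probe of RT1-Db1 had a log2 difference of −2.59 and its second probe one of −0.69.

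Of the 126 splits of the 10 arrays into groups of 5, 100 were run, the real one included. Only 1 split, the real one, gave as many genes higher (222, highest other split 1), lower (419, highest other 1) or changed at least 2-fold (124, highest other 1). A random split of the arrays therefore does not account for these counts. The splits ignored the slide, with which the real one nearly coincides, so they cannot part strain from slide. Chance cannot be excluded for the number of gene lists past the threshold. There 74 of the 100 splits gave 5 or more, and the highest other split gave 15.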

How the results depend on the processing

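The slide as a random effect and the fit on slide 2 alone were chosen after seeing the data. Genes higher numbered 351 with quantile normalisation, 368 with median scaling, 423 with the authors' values, 376 over all probes and 106 with a 1.5-fold minimum; lower ones 747 over all probes and 258 with that minimum. Higher and lower genes were 12 and 32 with the slide as a block, 14 and 38 on slide 2 alone, 669 and 1110 with the title number as a random block (correlation −0.16) and 1350 and 2101 with the slide as a random effect (−0.19). Genes changed at least 2-fold numbered 55 with normexp, 44 with the block, 52 on slide 2 and 259 over all probes. The normexp offset of 50 shrinks the log2 differences of dim genes. That offset, fewer arrays on slide 2, more tests over probes and the stricter minimum change these counts by construction. So does a negative correlation within blocks that hold 1 strain, as all title numbers and slides 1 and 3 do. It shrinks the standard error of the strain difference, so the higher counts with random effects are no added evidence for such a difference. Otherwise the cause was not tested. Leaving out 1 array gave 125 to 237 higher, 218 to 512 lower, 103 to 148 changed 2-fold and 3 to 7 lists.

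With an estimated correlation 0 lists passed in camera, against 5 with the preset one and 6 in fry. The medians and adjusted p then were −0.53 (0.757) for interferon, and, all at 0.772, −0.41 for MHC, −0.44 for macrophages, −0.37 for extracellular matrix and −0.27 for mast cells. With fry, macrophages (−0.44, 0.107), extracellular matrix (−0.37, 0.274) and mast cells (−0.27, 0.0688) missed the threshold. Fry also passed 4 lists that camera over all arrays did not: tight junctions (0.0757, 0.0380), lymphoid chemokines (−0.12, 0.0429), genes reported to differ between the strains (−0.0291, 0.0380) and the renin-angiotensin system (−0.18, 0.0429), whose direction in fry was upward, against the downward camera test. The matrix list missed the threshold with array weights (−0.20, 0.0941), and mast cells with normexp (−0.0388, 0.181), quantile normalisation (−0.19, 0.0665) and the authors' values (−0.19, 0.0542). Cell division passed with the mean of all probes (−0.14, 0.0450) and oxidative phosphorylation with the authors' values (−0.0736, 0.0286). With the block, where the difference rests on SHR 2-1, the medians were 0.17 for endothelium and −0.0671 for oxidative phosphorylation. On slide 2 alone, with 1 SHR array, the median of oxidative phosphorylation was −0.0671. Leaving out 1 array gave medians of −0.23 to −0.0892 for cell division, −0.46 to −0.17 for matrix, −0.15 to −0.0318 for inflammatory cytokines, −0.20 to −0.0777 for lymphoid chemokines and −0.31 to −0.22 for mast cells. The causes were not tested. The other 659 list results that had not passed, and 109 that had, kept their side.

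Of 64 named genes past the threshold, 46 kept their call without each array in turn, 55 under the 4 other scalings and 21 with the slide as a block. Another probe was present for 12 of the 64: 6 kept their call in it, 5 lost it with the same sign, namely Col1a1 (−0.19, adjusted p = 0.360), Cxcl12 (−0.61, 0.0864), Cyp11b3 (−0.14, 0.631), Map1lc3b (0.26, 0.419) and Slc4a4 (−0.35, 0.0730), and Rtel1 reversed (−0.54, 0.0838). The cause was not tested. No paired analysis was possible because the strains share no replicate number. List tests were not run with random blocks, no slide held at least 2 arrays of both strains, and 3 named genes had no value under the filter on all arrays. Signal over background limits Or4k44, Cyp2j10 and Efnb2.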

Other observations

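The genes in this part were named after their values had been seen. The tests of scaling, slide and neighbouring genes were also chosen after the results were seen, while that of probes with a strain variant was written before its result.

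Outside the gene lists and the named genes, 88 genes differed at least 2-fold, 15 higher and 73 lower in SHR, of which 70 kept their call without each array in turn and 13 passed with the slide as a block. The Hedgehog ligand gene Shh was lower (log2 difference −1.85 ± 0.13 SE, n = 5 per strain) and passed with the block (−1.81, adjusted p = 0.00880). Kcne1, a potassium channel subunit related to Kcne2, was lower (−1.57 ± 0.25), where Kcne2 had risen. Nmb, which encodes the peptide neuromedin B, was lower by a log2 difference of −1.98 ± 0.29 and above background on 4 of 5 SHR arrays, and Azgp1, the secreted zinc-alpha-2-glycoprotein, by −1.43 ± 0.17. Among higher genes were Scara3 (1.36 ± 0.15) and its neighbour Clu, the secreted chaperone clusterin (1.21 ± 0.17), and Trpv6, an epithelial calcium channel (1.03 ± 0.13). With the block Kcne1, Azgp1 and Trpv6 (adjusted p = 0.0737 each), Clu (0.101), Scara3 (0.107) and Nmb (0.327) did not pass.

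Whether genes of leukocytes are more frequent among the 73 lower genes than among all genes was not tested, and the T and NK cell list did not pass (median −0.04). Klra1 (−1.96 ± 0.20 SE, n = 5 per strain) and Ly49s7 (−1.22 ± 0.14) encode lectin-like receptors of natural killer cells, and Klra1 was above background on 3 of 5 SHR arrays. Both belong to a family of closely related genes, and whether their probes separate its members was not tested. Syk, a kinase of immune receptor signalling, was at −1.14 ± 0.15, Hk3 at −1.40 ± 0.18 and the formyl peptide receptor Fpr1 at −1.07 ± 0.11. Mcpt9, a mast cell protease, was at −1.04 ± 0.10. Each of these kept its call without each array in turn, and 0 of the 6 passed with the slide as a block (adjusted p from 0.0763 for Fpr1 to 0.476 for Syk).

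Of 1016 olfactory receptor genes tested, 37 were lower and 4 higher in SHR, while over all 14711 genes 419 were lower and 222 higher, 4.36% in all. Whether the family differs from all genes was not tested. In the 37 lower ones the median of slide 3 minus slide 2 within WKY was 0.20, and that of slide 1 minus slide 2 within SHR −0.26. Within slide 2 all 37 were lower in SHR, with a median of −0.37 that rests on SHR 2-1. The median of the family was −0.07, and it was 0.00 with normexp, −0.01 with quantile normalisation, −0.03 with median scaling, −0.01 with the authors' values and 0.07 with the slide as a block. The counts of lower and higher genes were 20 and 6, 30 and 11, 29 and 8, 34 and 11, and 4 and 0 in those fits.

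Genes that differ at least 4-fold numbered 24, of which 8 were higher. A strain variant under the probe is a candidate explanation for part of them. Another probe was present for 5 of these genes and showed a median log2 difference of 0.14 in the direction of the first, whose median was 2.59. The corresponding values were 0.42 against 1.26 for genes changed 2-fold to 4-fold and 0.18 against 0.55 below 2-fold. Of the 24 genes, 20 passed with the slide as a block, with sizes such as 6.25 for Cbr1 and −4.87 for Pcyox1l, which speaks against the slide as the whole cause, but only SHR 2-1 shares a slide with WKY and its array also entered the choice of these genes, so slide and strain cannot be told apart; a difference in expression between the strains stays open too.

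More genes were lower than higher in SHR, 65.4% of the calls. The share depended on the scaling and was 49.6% with scaling to the median. The change came mainly from the higher genes, which numbered 368 instead of 222, while the lower ones numbered 362 instead of 419, so the scaling may account for the unequal share but not for the lower genes as such. The slide may contribute as well. Within WKY alone, 40 genes were called higher and 2 lower on slide 3 than on slide 2, and slide 3 held no SHR array. Of the 241 genes called lower from slides 1 and 3 alone, where strain and slide coincide, 63.9% were lower on slide 2, against 100% of the 35 called higher (Fisher's exact test, p = 8.1e-07). All signs on slide 2 rest on SHR 2-1, and genes on an array are not independent, so this p does not measure support for a slide effect. The median difference over all genes was 0.03 with the slide as a block and −0.02 without it, an offset that moves all signs alike. A strain difference in the number of lower genes was not excluded.

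The hypothesis that genes changed at least 2-fold lie side by side, as local strain differences in the genome would give, was tested with 10000 random gene sets. Over all tested genes 4 neighbouring pairs were found against 1.04 on average (permutation p = 0.0225). Without MHC and olfactory receptor genes, which lie in clusters, 3 were found against 0.849 (permutation p = 0.0532), so the hypothesis was not decided. These 3 pairs were Setd4 with Cbr1, Scara3 with Clu and Ifi27 with Ifi27l2b, each changed in the same direction.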
